A study of Mus musculus with 8 samples.

How the data were processed

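RNA of B16-F10 cells, a mouse melanoma line, was measured in 8 libraries, 1 per condition. The cells had grown for 24 hours on the extracellular matrix left behind by smooth muscle cells. Before they were lysed, the smooth muscle cells had received siRNA for 72 hours and were then kept for another 72 hours in 1 of 2 media, abbreviated SFM and TCM in the labels. The series title names B16-F10 tumor conditioned media, which is read here as TCM. The 4 siRNA treatments were siNT, siKLF4, siFN, and siKLF4 together with siFN, written siKLF4-siFN.

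The authors deposited FPKM values (fragments per kilobase of gene, scaled to library size), with 46477 rows named by gene symbol and 1 column per library. Per the submitters' processing notes, STAR 2.4.1d and Partek were used with the mouse build mm10. The counting rule, the gene annotation, the strand setting and any scaling between libraries are not given in the sources used here. Reads of processed pseudogenes and other near-identical copies can be split by such counting, so values of genes ending in -ps are uncertain, as are those of overlapping genes. The table has 27 rows whose names look like dates, as spreadsheet programs make from some symbols. Of these names, 2 belong to more than 1 row. Those rows were kept apart and unnamed, although the plan was to sum rows of one symbol, because different genes can end up under one date.

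Symbols were matched to the GENCODE M21 annotation of GRCm38, the same assembly as mm10. A match was found for 42026 rows (90.4%), and coordinates are 1-based on that assembly. Of the 6917 genes tested, 94.9% had a length and a GC content.

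Depth was estimated from the FPKM steps of low values in genes with a single annotated transcript and over 600 nucleotides. For each library, the step was chosen that put the largest share of these values near whole numbers. Between 44.2% and 48.3% of them then lay within 0.05 read of a whole number. A step fixed beforehand would give 10% by chance, but a step chosen on the same values can give more. The recovered depths are therefore approximate, and no comparison of conditions was tested on counts. Reads rebuilt from them were used only to set pairs of libraries against counting noise, and the shares of genes beyond that noise are as approximate as the depths. They ranged from 11600000 to 23000000 reads. At an FPKM of 1, a gene of 2 kb then has 23.2 to 46.1 reads and a counting error of 14.7% to 20.8%. Counting error leaves out the variation between cultures, which 1 library per condition cannot show.

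Values were analysed as log2(FPKM + 1) in genes with a mean FPKM of at least 1 over the 8 libraries, and differences on this scale understate the change of low genes. limma 3.58.1 in R 4.3.3 was used with a variance trend, two-sided tests and Benjamini-Hochberg adjustment at 0.05. Media, siKLF4 and siFN were each tested in an additive model with 4 residual degrees of freedom. In that model the libraries that share a level stand in for replicates, and any interaction enters the residual. Each of the 3 interactions was tested in a model with that term added and 3 residual degrees of freedom. Adjusted p-values below are from limma. No label says that libraries came from separate cultures of one condition, so p-values measure only the spread between these libraries. Pairs of single libraries were not tested. For them, genes differing by at least 1 on the log2 scale were counted, and the median of a gene list was placed among 10000 random lists of the same size matched on mean expression.

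The 26 gene lists, the models, most alternatives and the naming rule were fixed before the data were examined, and 20 lists had at least 5 measured members. Lists were tested with camera in limma at a preset correlation between genes of 0.01, again with an estimated correlation, and with fry. For a main effect with too few genes past the threshold, the named genes are the 5 with the smallest p in each direction. For an interaction they are the 3 with the smallest p in each direction. For a pair of libraries they are the 8 largest rises and falls among genes with an FPKM of at least 5 in either library. From each list, up to 4 members with the smallest p may be named, and Klf4 and Fn1 are always given. Gene models without an official name were counted but passed over, and some genes that the rule names are not reported here.

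The models were tested on simulated data with independent noise in 6917 genes, at the variance limma gave each gene after drawing it toward the trend. Over 5 runs, 250 genes were planted at each log2 change from 1 to 4. So many large changes loosen the adjusted threshold. For the media effect, 84.8% of genes planted with a log2 change of 1 were recovered, and 100% of those with a change of 2. For the media by siFN interaction the shares were 53.6% and 95.6%. Wrong calls made up 6.34% and 6.03% of all calls in these simulations. The recovered shares hold for these settings and are not the power of the real fits, in which genes moved together. Alternatives covered the pseudocount, the filter, scaling between libraries, the variance trend, covariates and leaving out each library. Taking the interaction apart, testing lists in the interactions, correcting for gene length and GC content, and keeping only protein-coding genes were added after seeing the data, as were simulations with 1 library left out and simulated ranges of the shift toward SFM siNT under other settings. Without 1 library, its combination of medium and siFN is left with 1 library, which is assumed to vary like the others. Python 3 drawing used matplotlib 3.10.9.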

Results

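B16-F10 melanoma cells were sequenced after growth on smooth muscle cell matrix made under 2 media and 4 siRNA treatments, which gave 8 libraries with no replicates. Each level of medium, siKLF4 and siFN was thus represented by 4 libraries. The estimated depth was 23000000 reads for SFM siNT, 11600000 for SFM siKLF4, 21000000 for SFM siFN and 13000000 for SFM siKLF4-siFN. It was 13900000 reads for TCM siNT, 14300000 for TCM siKLF4, 19400000 for TCM siFN and 19800000 for TCM siKLF4-siFN.

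The siRNA had been given to the smooth muscle cells, so Klf4 and Fn1 in the melanoma cells do not check the labels. Klf4, a transcription factor, had an FPKM of 6.84 in SFM siNT, 6.56 in SFM siKLF4, 8.62 in SFM siFN and 5.79 in SFM siKLF4-siFN. It was 8.04 in TCM siNT, 6.75 in TCM siKLF4, 8.13 in TCM siFN and 7.80 in TCM siKLF4-siFN. Fn1, which encodes fibronectin, stood at 1.82, 2.32, 3.12 and 3.10 in the SFM libraries in the same order, and at 2.93, 2.63, 2.54 and 2.56 in the TCM libraries. The siKLF4 difference of Klf4 was -0.21 ± 0.12 (SE, log2, adjusted p = 1.0), and the siFN difference of Fn1 was 0.17 ± 0.14 (adjusted p = 0.993). Among markers of other cell types, 2 of 20 smooth muscle markers reached a mean FPKM of 1. These were Des, at 1.07, and Mcam, an adhesion molecule also known from melanoma cells, at 23.96. Mcam stood at 33.6 in SFM siKLF4-siFN and 33.05 in TCM siNT, and between 18.8 and 23.2 in the other libraries. A mean of 1 was also reached by Gsn (1.30) among 20 fibroblast markers, Eng (4.74) among 16 endothelial markers and Cd68 (2.93) among 19 leukocyte markers. Acta2 was listed at 0 in all 8 libraries, but so were all 15 mitochondrially encoded transcripts in the table, so a 0 here need not mean low expression.

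Genes of cell division set the libraries apart. The mean of 26 mitosis genes, centred per gene on the log2 scale, was 0.61 in SFM siNT, 0.54 in SFM siKLF4, 0.57 in TCM siKLF4, 0.57 in TCM siFN and 0.59 in TCM siKLF4-siFN. It was -1.12 in SFM siFN, -1.18 in SFM siKLF4-siFN and -0.57 in TCM siNT. Genes of the amino acid and ER stress response lay the other way, with means of 0.21, 0.26 and 0.23 in those 3 libraries and below 0 in the others. The ratio of Gm10925 to Gm29216, nearby nuclear copies of mitochondrial sequence picked out after their values were seen, was 0.247, 0.0769 and 0.249 in those 3 libraries and 0.231 in TCM siKLF4, against 0.525 to 0.777 in the other libraries. The first principal component held 57.9% of the variance and placed SFM siKLF4-siFN at 35.2, SFM siFN at 17.6 and TCM siNT at 7.36, with the other libraries between -15.7 and -5.90. Over all tested genes, the media by siFN contrast carried 38.0% of the variance, media 20.04%, siFN 10.3% and siKLF4 7.53%.

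**Figure D1:**
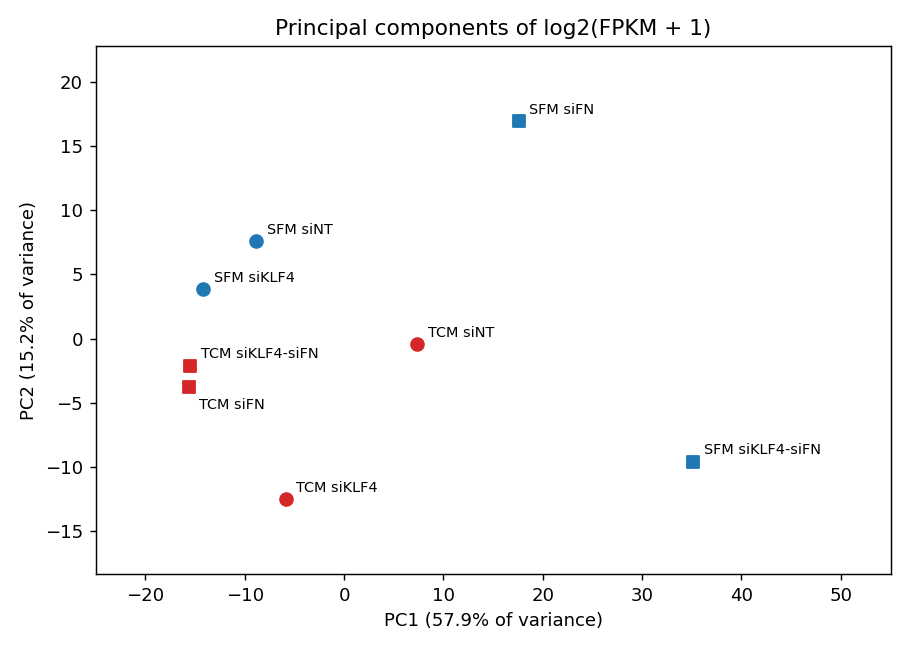
Principal components of log2(FPKM + 1) over 6917 genes, with each point a library, blue for SFM, red for TCM and squares for libraries with siFN. The first axis carries 57.9% of the variance and places SFM siKLF4-siFN at 35.2 and SFM siFN at 17.6.

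The media effect asks whether matrix made in TCM gave another melanoma profile than matrix made in SFM. Pet117, an assembly factor of cytochrome oxidase, had the smallest p among genes with higher values in TCM, at 1.07 ± 0.15 (SE, log2, adjusted p = 0.254). It was followed by Safb2, AK157302, the splicing factor Srsf5 (0.49 ± 0.11) and Pet100, all of them higher in TCM in 4 of 4 matched pairs of libraries. Lower values with small p included those of the pseudogenes Spin3-ps, Cbfa2t2-ps1, Rps12-ps10 and Psmb7-ps2. None of these genes passed the test. All 26 mitosis genes had values above 0 (median 0.53) and so did all 20 S phase genes (median 0.42), but none passed, also when adjusted over the list alone. These values pool libraries with opposite signs. Without siFN, 25 of the 26 mitosis genes (median -0.56) and 18 of the 20 S phase genes (median -0.26) lay below 0. With siFN all of both lists lay above it (medians 1.69 and 1.12). The values without siFN average unlike pairs. The centred mitosis mean was 0.61 in SFM siNT and -0.57 in TCM siNT, but 0.54 in SFM siKLF4 and 0.57 in TCM siKLF4. The S phase mean was 0.328 in SFM siNT and -0.331 in TCM siNT, but 0.355 in SFM siKLF4 and 0.449 in TCM siKLF4. limma called 0 of 6917 genes, with 464 at an unadjusted p under 0.05 against 346 by chance. camera called 7 of 20 lists, among them S phase and mitosis, and none with an estimated correlation (mitosis adjusted p = 0.698 with an estimated correlation, S phase adjusted p = 0.610 with an estimated correlation). That correlation, 0.955 for mitosis and 0.960 for S phase, was taken from the residual of the additive model. This residual holds the media by siFN contrast, along which these genes moved together. The missing calls of genes and lists therefore do not show that the medium had no effect.

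The siKLF4 effect asks whether matrix of smooth muscle cells given siKLF4 changed the melanoma cells. The smallest p among higher values belonged to Hmgb1-ps2, Rpl31-ps10, Ppp1r35 (0.48 ± 0.12, SE, log2), Pet117 and Rpl10-ps1. Among lower values it belonged to Spin3-ps, Tmem107 (-0.43 ± 0.14), the ribosomal protein gene Rpl34 (-0.49 ± 0.17), Psmb7-ps2 and Npm3-ps1. No gene among these passed (adjusted p = 1.0 for each). In the cholesterol and fatty acid synthesis list, 27 of 32 members had values above 0 (median 0.11), and in the list of cytosolic ribosomal proteins 42 of 58 lay below 0 (median -0.08). These values pool unlike pairs. The centred cholesterol mean was 0.151 in SFM siNT and 0.068 in SFM siKLF4, but -0.210 in TCM siNT and 0.116 in TCM siKLF4. It was -0.184 in SFM siFN and 0.009 in SFM siKLF4-siFN, and 0.022 in TCM siFN and 0.027 in TCM siKLF4-siFN. The ribosomal mean was higher with siKLF4 only from TCM siFN (-0.110) to TCM siKLF4-siFN (-0.069). limma called 0 genes, with 84 at an unadjusted p under 0.05 against 346 by chance. The residual of the additive model, shared by the main effects, holds the media by siFN contrast (38.0% of the variance). The 0 calls therefore do not show that siKLF4 had no effect. camera called 6 lists, and none with an estimated correlation (lowest adjusted p = 0.873 with an estimated correlation). The correlation was estimated from that residual, so the missing list calls do not show it either.

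The siFN effect asks the same for siFN. Higher values with the smallest p were those of Rpl13a-ps1, Oxld1 (0.37 ± 0.09, SE, log2), the histone gene Hist1h4h, Rps13-ps4 and Yam1. Lower values with the smallest p were those of Cbr2, Mrps36-ps2, Cebpd (-0.33 ± 0.10), Nppb (-0.65 ± 0.21) and Ctgf (-0.52 ± 0.17), a target of YAP that encodes a matrix-associated growth factor. None passed (adjusted p = 0.993 for each). All 10 measured genes of the invasive melanoma state list and all 20 S phase genes had values below 0, with medians of -0.33 and -0.35. These values pool both media. On SFM matrix all 20 S phase genes lay below 0 (median -1.12), and on TCM matrix all 20 above it (median 0.35). The TCM value again averages unlike pairs. The centred S phase mean was -0.331 in TCM siNT and 0.402 in TCM siFN, but 0.449 in TCM siKLF4 and 0.425 in TCM siKLF4-siFN. Of the invasive state genes, 7 lay below 0 on SFM matrix (median -0.74) and 5 on TCM matrix (median -0.0227). limma called 0 genes, with 84 at an unadjusted p under 0.05 against 346 by chance. The same residual was used, so the 0 calls do not show that siFN had no effect. camera called 11 lists, and none with an estimated correlation (lowest adjusted p = 0.483 with an estimated correlation). The correlation was estimated from that residual, so the missing list calls do not show it either. Without TCM siNT, 1 gene was called, the unnamed model Gm19918, chosen for mention after its value was seen.

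The media by siFN interaction asks whether the TCM to SFM difference changed when the smooth muscle cells had received siFN. Here 496 of 6917 genes passed, 265 with a rise and 231 with a fall, where a rise means a larger TCM minus SFM difference with siFN than without it. Of them, 410 were protein coding and 51 were pseudogenes. Ddias on chromosome 7 (92857525 to 92874247) rose by 2.75 ± 0.19 (SE, log2, adjusted p = 0.0185). Atad2 rose by 2.90 ± 0.32 and Dlx6, a homeobox gene, by 1.73 ± 0.20. Cox6a2 (-2.52 ± 0.26), Nat8 (-1.81 ± 0.19) and Ifrd2 (-1.65 ± 0.18) fell, each with an adjusted p of 0.0375 as for Atad2 and Dlx6.

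Of 26 mitosis genes, 22 rose and none fell, with 25 adjusted over the list alone and a median of 2.25. Top2a, the topoisomerase of dividing cells, on chromosome 11 (98992943 to 99024189), rose by 3.97 ± 0.51. Its FPKM was 7.29 in SFM siNT, 9.14 in SFM siKLF4, 0.559 in SFM siFN, 0.187 in SFM siKLF4-siFN, 1.74 in TCM siNT, 5.82 in TCM siKLF4, 9.04 in TCM siFN and 9.12 in TCM siKLF4-siFN. Mki67, Ckap2 and Anln also rose, by 2.25, 2.22 and 1.82. Of 20 S phase genes, 12 rose, 18 adjusted over the list alone, with a median of 1.54. They included Rrm2 and Rrm1, subunits of ribonucleotide reductase (3.20 and 2.17), the helicase subunit Mcm4 (2.24) and Rpa2 (1.48). The adjusted p was 0.663 with an estimated correlation for both lists. TCM siNT had a mitosis mean of -0.57 and TCM siKLF4 of 0.57, so the interaction term averaged unlike libraries in TCM without siFN.

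Some pigment and cell state genes also passed in this model. Of 17 melanocyte differentiation and pigment genes, 5 rose, 6 adjusted over the list alone, including Mc1r, the melanocortin receptor (2.58), Myo5a (1.41), Tyr, which encodes tyrosinase (1.33), and Met, a growth factor receptor (1.26). Of 10 genes of the invasive melanoma state, 4 rose, 6 adjusted over the list alone: Nes (1.77), Sox9 (1.47), Anxa1 (1.26) and Vim (1.20). The adjusted p was 0.663 with an estimated correlation for both lists, while fry gave 0.0359 for the invasive state. Of 11 interferon response genes, Ifit2 (1.65) and B2m (1.35) rose, and adjusted over the list alone 7 rose and 2 fell (adjusted p = 0.696 with an estimated correlation). Of 21 p53 targets 2 rose, 6 adjusted over the list alone, namely Ercc5 (1.41), a repair nuclease, and Gtse1 (2.37), which is also a gene of dividing cells (adjusted p = 0.696 with an estimated correlation).

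Of 41 amino acid and ER stress response genes, 6 fell and none rose, 23 adjusted over the list alone, with a median of -0.76. They included Ppp1r15a (-1.92), the chaperone Hyou1 (-1.88), Trib3 (-1.39) and Wars (-1.26). The FPKM of Hyou1 was 15.1 in SFM siNT, 37.6 in SFM siFN, 32.3 in TCM siNT and 16.9 in TCM siFN. Of 37 lysosome and autophagy genes, Ctsl (-1.51) and Mcoln1 (-0.83) fell, with 0 adjusted over the list alone. Of 58 cytosolic ribosomal protein genes none passed, with a median of -0.41. The adjusted p with an estimated correlation was 0.663 for the stress list, 0.735 for the lysosome list and 0.663 for the ribosomal list.

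**Figure D2:**
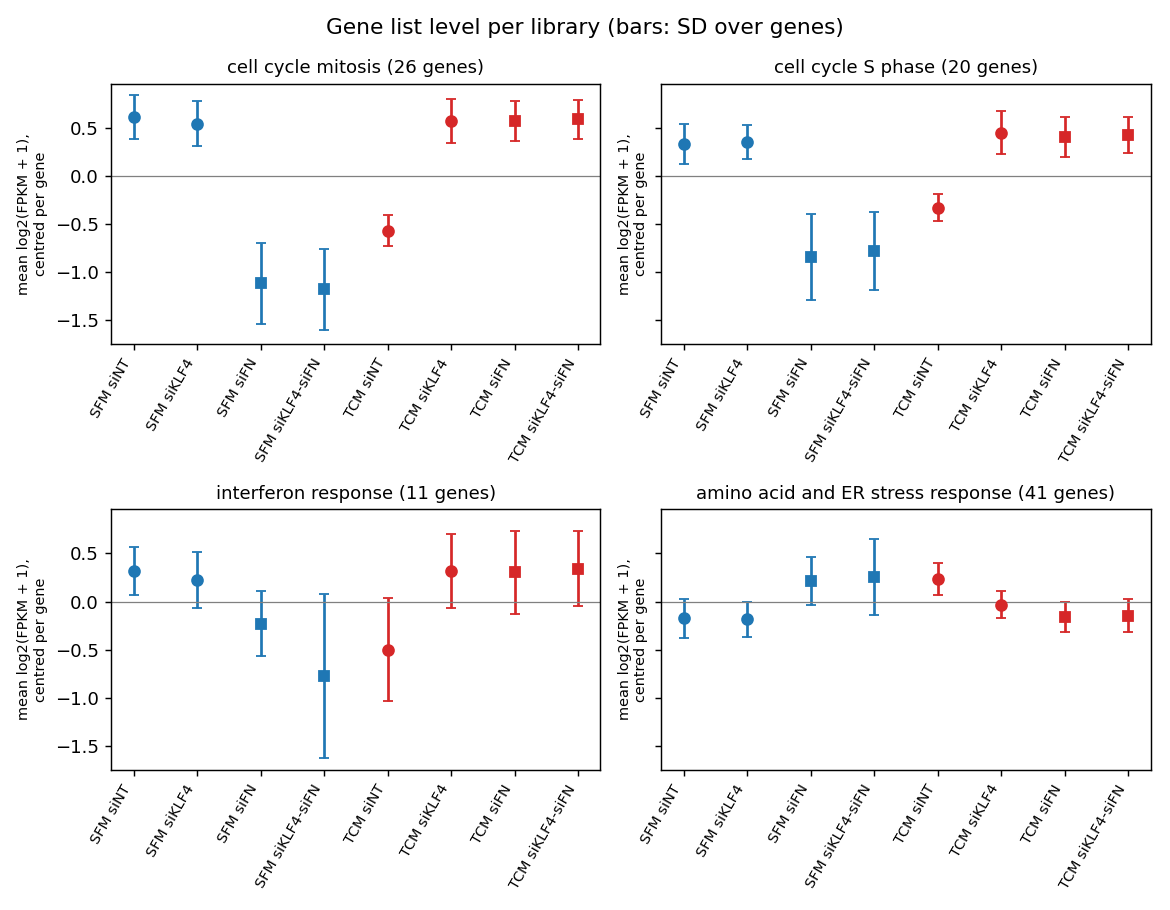
Mean log2(FPKM + 1) of 4 gene lists in each library, centred per gene, with bars for the SD over the genes of the list, blue for SFM, red for TCM and squares for libraries with siFN. The mitosis mean lies at -1.12 in SFM siFN, -1.18 in SFM siKLF4-siFN and -0.57 in TCM siNT, and above 0 in the other libraries.

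The number of interaction calls changed with the library left out. Without SFM siNT, SFM siKLF4, SFM siKLF4-siFN, TCM siFN or TCM siKLF4-siFN, limma called 0 genes in each case, without TCM siNT 51, and without SFM siFN 2065, with 1338 to 3184 genes at an unadjusted p under 0.05 over the 8 fits. Each of these fits has 2 residual degrees of freedom instead of 3. All 496 genes kept their direction in each of them, with a median absolute interaction of 1.13 to 1.47 against 1.31 with 8 libraries. That lends no support, because the genes were selected in these same 8 libraries and the fits share most of them. In further simulations, a planted interaction of 1 was recovered in 32.1% of genes with 7 libraries and 60.8% with 8, and one of 2 in 95.4% and 97.2%. Those simulations also drew genes independently, so the shares are not the power of the real fits. A pseudocount of 0.1 gave 0, no filter 14, a mean FPKM of at least 5 gave 251, and protein-coding genes alone gave 1006.

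Taken apart in the same model, the TCM to SFM difference with siFN involved 1172 genes, 582 higher in TCM and 590 lower. The siFN difference on SFM matrix involved 479 genes, 219 higher and 260 lower with siFN. limma called 0 genes for the TCM to SFM difference without siFN (627 at an unadjusted p under 0.05) and 0 for the siFN difference on TCM matrix (391 unadjusted). The difference between these pairs of effects is the interaction tested above. All these fits take TCM siFN and TCM siKLF4-siFN as separate libraries. They were the closest of 28 pairs, and 1 RNA sequenced under both names is not excluded. In that case the residual would hold too little spread and the counts would be too high. The count of 1172 became 0 without SFM siKLF4-siFN, TCM siFN or TCM siKLF4-siFN, 495 without SFM siNT, 501 without SFM siKLF4 and 2243 without SFM siFN, and the count of 479 became 0 without SFM siNT, SFM siKLF4 or SFM siKLF4-siFN, 70 without TCM siFN or TCM siKLF4-siFN and 1835 without SFM siFN. With no filter the counts were 14 and 10, against 8 and 13 for the contrasts with 0, a mean FPKM of at least 5 gave 626 and 259, and a pseudocount of 0.1 gave 281 for the siFN difference on SFM matrix.

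The media by siKLF4 and siKLF4 by siFN interactions ask whether siKLF4 acted differently by medium or by siFN. For the former, genes with small p included the pseudogenes Rpl17-ps8, Rpl30-ps10 and Hmgb1-ps5 above 0, and Rpl10-ps1 and Rps12l1 below 0. For the latter, they included Rpl27a-ps1 and AI413582 above 0, and Ccnd3-ps, Rn7s2 and Rasl2-9 below 0. None passed (adjusted p = 1.0). limma called 0 genes in either, with 78 and 40 at an unadjusted p under 0.05 against 346 by chance. All 26 mitosis genes lay above 0 for the former (median 0.69) and below 0 for the latter (median -0.53). For the former, all 11 interferon genes and 42 of 49 oxidative phosphorylation genes also lay above 0, and 35 of 41 stress genes below it. camera called 5 of 20 lists in each, and none with an estimated correlation (lowest adjusted p = 0.762 and 0.879 with an estimated correlation). The media by siFN contrast lies in the residual of both models, from which the correlation was also estimated. The missing calls therefore do not show that these interactions are absent.

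Among single libraries, TCM siNT against SFM siNT shows the medium with the control siRNA, without a replicate check. Cell cycle and interferon-induced genes were lower in TCM siNT: Ccnb1 had an FPKM of 2.04 against 9.38, Ccna2 3.23 against 12.7, Top2a 1.74 against 7.29, Isg15 4.69 against 17.5, and the chemokine gene Cxcl10 7.50 against 42.8. Ccng1, Rn7s1 and Mpc1-ps were the other large decreases. Higher in TCM siNT were Ppp1r15a (129 against 58.8), Gadd45a (94.4 against 43.8), Acot2, the lipid droplet gene Plin2, Hyou1, Malat1, Hist2h2aa2 and Rn7s2. In all, 168 genes differed by at least 1 on the log2 scale, 39 higher and 129 lower in TCM siNT. The 28 pairs of libraries gave 20 to 710 such genes, with a median of 150.5. The mitosis list had a median of -1.23, below all 10000 random lists, and 18 of its 26 genes were lower by at least 1. S phase genes had a median of -0.71 and interferon genes of -0.62, also below all random lists, and the stress list a median of 0.36, above all of them. Oxidative phosphorylation genes (median -0.24) lay below all of them too. Random lists draw unrelated genes, while genes of a list can move together between 2 single libraries. These places therefore carry no error rate.

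Libraries with siKLF4, siFN or both were then set against TCM siNT, which asks what each siRNA did on TCM matrix. In TCM siKLF4, Cxcl10 was at 53.002 against 7.50, Isg15 at 20.6 against 4.69, Ccl5 at 7.99 against 1.62, Ccnb1 at 8.30 against 2.04 and Rrm2 at 28.004 against 8.79. Hist2h2aa1, Ckb and Cdca3 were the other large increases, and Acot2, Malat1, Plin2, Lgals3, Ech1, Rps15a-ps6, Maoa and Gadd45a the largest decreases. In TCM siFN, Cxcl10 was at 50.8, Top2a at 9.04, Isg15 at 18.6, Ccnb1 at 8.33 and Rsad2 at 11.2 against 3.04, followed by Ccng1, Ccna2 and Cox20-ps. Acot2, Plin2, Lgals3, Ech1, Cyb5r1, Chchd10, Pla2g2e and Htra2 were lower. In TCM siKLF4-siFN, Cxcl10 was at 51.2, Top2a at 9.12, Isg15 at 18.2 and Hmgb2 at 21.7 against 6.502, with Yam1, Rn7s1, Ccng1 and Cdca3. Acot2, Plin2, Chchd10, Lgals3, Mir6236, Cyb5r1, Ech1 and Eno2 were lower.

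The counts of genes differing by at least 1 were 123 for TCM siKLF4, 129 for TCM siFN and 141 for TCM siKLF4-siFN. Mitosis medians were 1.30, 1.14 and 1.18 in that order, each above all 10000 random lists, and stress medians were -0.21, -0.41 and -0.38, each below all of them. These comparisons share TCM siNT, so their likeness is partly built in, and the limit of the random lists given above applies here as well.

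**Figure D3:**
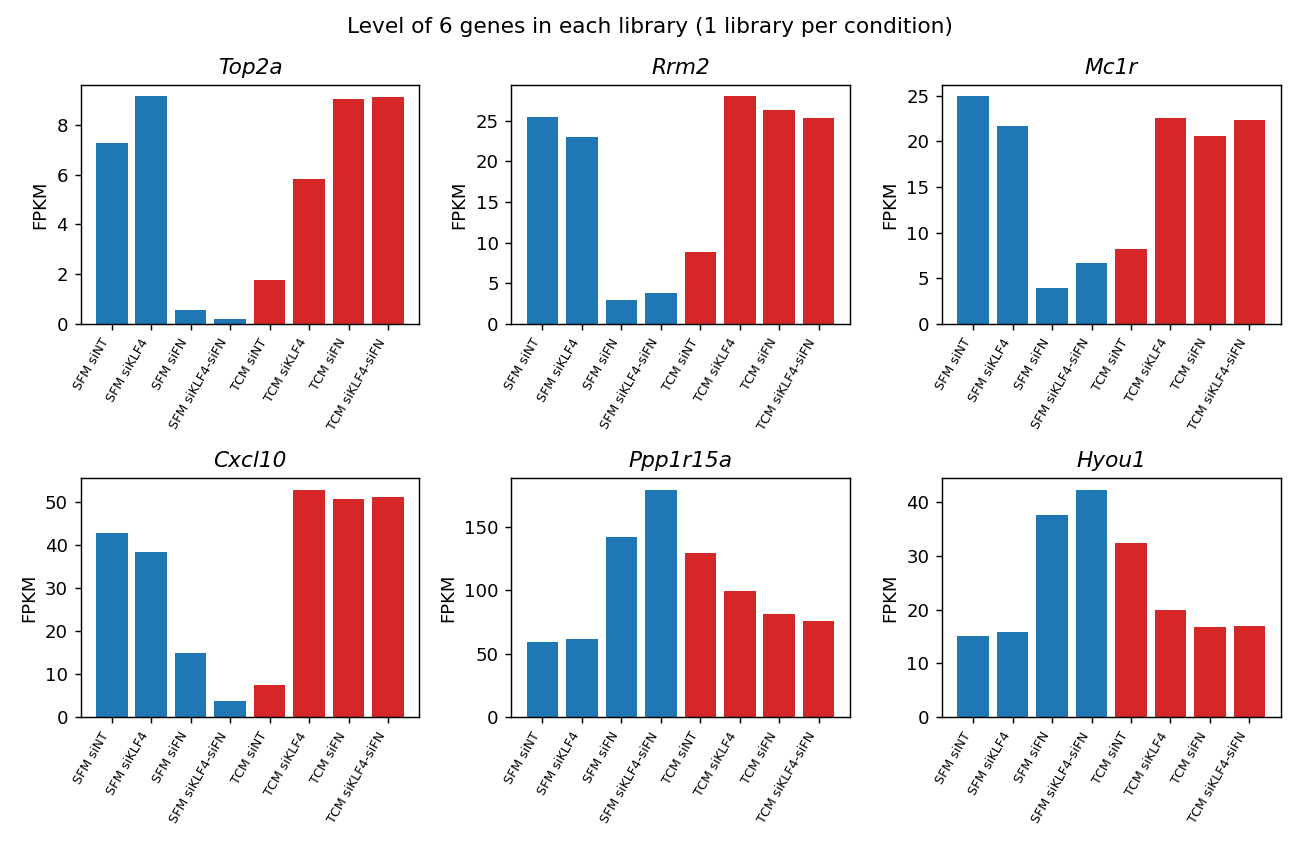
FPKM of 6 genes in each of the 8 libraries, with bars from 0, blue for SFM and red for TCM, and no error bars because each condition has 1 library. Top2a lies at 0.559 in SFM siFN and 0.187 in SFM siKLF4-siFN, against 9.04 in TCM siFN.

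The shift back toward SFM siNT asks how far each library lay from TCM siNT in the direction of SFM siNT, over the 168 genes above. A slope of 0 is the level of TCM siNT, and 1 that of SFM siNT. It was 0.566 in TCM siKLF4, 0.545 in TCM siFN and 0.602 in TCM siKLF4-siFN. Unrelated simulated libraries gave 0.498 (0.417 to 0.574 over 1000 draws), because TCM siNT enters both sides. The simulation drew genes independently, whereas genes moved together here (estimated correlation 0.955 in the mitosis list for the media effect). The simulated ranges and the bootstrap over genes can therefore be too narrow, and a place inside or above a range decides nothing. TCM siKLF4 and TCM siFN lay inside that range, and TCM siKLF4-siFN above it, but these places changed with the settings. At a pseudocount of 0.1 all 3 lay above the range simulated for it (0.624, 0.609 and 0.664, against 0.433 to 0.573), and at a pseudocount of 5 (0.506, 0.560 and 0.585, against 0.352 to 0.634) or a mean FPKM of at least 5 (0.549, 0.562 and 0.603, against 0.381 to 0.623) all 3 lay inside. On SFM matrix the slope was 0.726 with siKLF4, 0.305 with siFN and 0.180 with both. The last was 0.0843 at a pseudocount of 0.1 and 0.0873 at 5, within its bootstrap interval over genes (0.0515 to 0.301), and the one with siKLF4 was 0.795 at 0.1, outside its own (0.663 to 0.784).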

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

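The depth tests, their bounds and the comparison of TCM siFN with TCM siKLF4-siFN were chosen after the results they bear on were seen, as were the list tests in the interaction. Depth was tested in 3 forms in turn, first by the level of the shallowest library (SFM siKLF4, mitosis mean 0.54), then as a covariate, which was first read as leaving depth open, and last by the share of variance, which is the form used below. A test of the difference itself, the media by siFN interaction, singled out 496 genes. The named genes were Ddias (2.75), Atad2 (2.90), Dlx6 (1.73), Cox6a2 (-2.52), Nat8 (-1.81) and Ifrd2 (-1.65), all as log2 interactions. The lists called by camera at its preset correlation had median interactions of 2.25 for mitosis, 1.54 for S phase, 1.35 for interferon response, 0.78 for pigment, 0.69 for the invasive state, 0.61 for p53 targets, -0.31 for lysosome, -0.41 for ribosomal proteins and -0.76 for amino acid and ER stress. None was called with an estimated correlation.

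For the interaction, 1 of 100 relabellings of the 8 libraries over the design, the real one, gave as many genes. The highest other gave 316. With 100 relabellings the lowest share that can be reached is 1 in 100, and the interaction was 1 of 6 results looked at. Chance labelling is therefore not excluded for the count, which also changed with the library left out. For the other results chance cannot be excluded by unadjusted counts either. As many genes came from 28 relabellings for media (464, highest other 2339), 72 for siKLF4 (84, highest other 2205), 77 for siFN (84, highest other 1856), 71 for the media by siKLF4 interaction (78, highest other 2152) and 99 for the siKLF4 by siFN interaction (40, highest other 1673). The relabellings with several times the real count point to a structure of the libraries.

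The mitosis genes stand for this pattern. Gene length and GC content as its whole cause are argued against, since after correcting each library the median interaction was 2.22 against 2.25 before, the lower quartile was 1.80, and 22 of 26 genes still passed. Depth as the whole cause is argued against too: the best rising or falling function of depth took a median of 0.201 of the variance of these genes (upper quartile 0.234, with Pttg1 the exception at 0.967), and with depth as a covariate the median interaction was 1.98 (lower quartile 1.56), although 0 genes passed with 2 residual degrees of freedom left. Exchanged media names in the 4 siFN libraries stay open: the bound set beforehand was that fewer media genes after the exchange would exclude it, and 1 gene (Ddias) passed, yet that bound was wrong because the exchange tests the same contrast as the interaction and only moves the media term into the residual. An effect of siFN that depends on the medium may hold, but by itself it does not account for the whole pattern. TCM siNT and TCM siKLF4 both lacked siFN, and their mitosis means were -0.57 and 0.57, each from 1 library. In the media by siKLF4 interaction all 26 mitosis genes also lay above 0 (median 0.69), although none passed. With 1 library per condition, effects of siFN, siKLF4 and the medium stay untested against culture-to-culture differences in growth.

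TCM siFN and TCM siKLF4-siFN were the closest of the 28 pairs. Among 582 single-transcript genes, with reads rebuilt from approximate depths, 12.5% differed beyond counting noise, against 5% by chance. The exact 95% interval was 9.96% to 15.5%, which takes genes as independent. The median gene, however, had a squared difference, scaled to counting noise, of 0.47, where counting noise alone gives 0.45. For SFM siKLF4 and TCM siFN that median was 0.65. Among all tested genes, 20 differed by at least 1 on the log2 scale between TCM siFN and TCM siKLF4-siFN. One RNA sequenced under both names could give these values if library preparation added a little spread, and so could 2 cultures with like profiles. They cannot be told apart, since no condition was sequenced more than once.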

How the results depend on the processing

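The length and GC correction, the protein-coding restriction, the split of the interaction and the simulated ranges at other settings were chosen after seeing the data. limma called 0 genes for the media, siKLF4 and siFN effects and for the media by siKLF4 and siKLF4 by siFN interactions under every alternative run, except 1 gene for siFN without TCM siNT. Leaving out each library gave 0 to 1 for siFN and 0 to 2065 for the media by siFN interaction. The media by siFN interaction, with 496 genes, had 0 at a pseudocount of 0.1 (2282 unadjusted), 14 with no filter, 251 at a mean FPKM of at least 5 and 1006 among protein-coding genes alone. The cause of these shifts was not tested. It had 603 at a pseudocount of 5, 729 after quantile normalization, 421 without the variance trend and 498 after the length and GC correction, of which 334 were shared with the 496. Median-of-ratios scaling gave 353, with 228 rises and 125 falls against 265 and 231. Of the 43 named interaction genes, none changed direction, although they were selected in these same libraries. Under median-of-ratios scaling 33 passed, at a pseudocount of 0.1 it was 0, and with no filter also 0. None of them is thus among the 14 genes called with no filter. For pairs of libraries, genes differing by at least 1 numbered 380 for TCM siNT against SFM siNT at a pseudocount of 0.1, 40 at 5 and 89 at a mean FPKM of at least 5. The same settings gave 272, 23 and 59 for TCM siKLF4, 332, 34 and 72 for TCM siFN, and 341, 32 and 74 for TCM siKLF4-siFN against TCM siNT. A pseudocount sets how far low genes can differ, and the filter at 5 removes genes that could be counted. The shift of SFM siKLF4 was 0.795 at a pseudocount of 0.1, outside its bootstrap interval, and the cause was not tested. At that pseudocount TCM siKLF4 (0.624) and TCM siFN (0.609) lay above the simulated range (0.433 to 0.573), and TCM siKLF4-siFN lay inside it at a pseudocount of 5 (0.585, 0.352 to 0.634) and a mean FPKM of at least 5 (0.603, 0.381 to 0.623). The simulated ranges take genes as independent, so these places decide nothing. Fn1 changed sign for the media effect without SFM siNT (-0.070) or TCM siNT (-0.0552), in a leave-one-out range of -0.070 to 0.120. For the siKLF4 effect it did so without SFM siNT, SFM siKLF4-siFN or TCM siFN, in a range of -0.0849 to 0.131, and after the length and GC correction (-0.018), with no call in any. Of the 7 media lists called by camera, 7 held under median-of-ratios scaling and 0 with fry. For siKLF4, 6 of 6 held under that scaling and 5 at a pseudocount of 0.1, and for siFN 8 of 11 held under each. With libraries paired by siRNA treatment, the media effect had 0 genes (345 unadjusted). Depth limits low genes most, with a counting error of 20.8% for a 2 kb gene at an FPKM of 1 in SFM siKLF4.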

Other observations

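Transcripts of the mitochondrial genome were listed at 0 in all 8 libraries for the 15 names in the table, while nuclear copies of mitochondrial sequence carried very high values. Gm28439, Gm28437, Gm10925, Gm28661 and Gm29216, unprocessed pseudogenes side by side on chromosome 1 between 24611535 and 24616197, were chosen after their values were seen. Their summed FPKM was 28082 in SFM siNT, 19831 in SFM siKLF4, 16836 in SFM siFN and 9181 in SFM siKLF4-siFN, and 13645, 10458, 16918 and 19211 in the TCM libraries in the same order. That is between 5.60% and 16.1% of all FPKM in a library. Gm10925 ranged from 366 in SFM siKLF4-siFN to 4927 in SFM siNT, and its ratio to Gm29216 was 0.525, 0.777, 0.247 and 0.0769 in the SFM libraries and 0.249, 0.231, 0.735 and 0.758 in the TCM libraries. It was thus low in the 3 libraries with low mitosis genes and in TCM siKLF4, whose mitosis genes were high. Reads of near-identical sequence cannot be assigned between these copies and the mitochondrial genome from this table.

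Genes of cholesterol and fatty acid synthesis lay lower in TCM siNT than in SFM siNT in 31 of 32 members, with a median of -0.36. Against TCM siNT, 32 lay higher in TCM siKLF4, 25 in TCM siFN and 26 in TCM siKLF4-siFN, with medians of 0.29, 0.27 and 0.23. Oxidative phosphorylation genes were lower in 42 of 49 members in TCM siNT against SFM siNT (median -0.24), and higher than in TCM siNT in 43, 28 and 31 members in the other TCM libraries in the same order. These are descriptions of single libraries that share TCM siNT.

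SFM siKLF4 lay close to TCM siFN and to TCM siKLF4-siFN, with 40 and 38 genes differing by at least 1 on the log2 scale and 17.9% and 17.1% of genes beyond counting noise, against 50 genes and 22.6% from SFM siNT. The percentages use reads rebuilt from approximate depths.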
